A study of Homo sapiens with 3 samples.

How the data were processed

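Total RNA of RH30 cells was hybridised, biotin-labelled, to Affymetrix expression arrays, 1 per condition: untreated, mutated PNA at 10 µM and anti-MYCN PNA at 10 µM, each at 12 hours. RNA was extracted with a phenol-based reagent and labelled by the one-cycle protocol, per the labels' protocols. The deposited values are linear signal intensities per probe set, made with MAS5 in GCOS per the submitters' processing notes, with 1 array per sample and no pooling stated. MAS5 combines the perfect match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The 2% trimmed mean, computed from the deposited intensities, was 500.2 on all 3 arrays, so the arrays had been brought to one level and no step had aligned their distributions. Scanner files, detection calls and scaling factors were not used here. Because MAS5 scales by 1 factor, an array whose brightest signals are relatively stronger keeps that difference: the highest gene signal was 50332 on the anti-MYCN PNA array and 33282 and 32467 on the untreated and mutated PNA arrays.

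Of 22277 probe sets, 62 are spike or control probe sets and 22215 measure genes. In a platform annotation of GEO, 19064 of these name 1 gene, 1043 several and 2108 none, and only the first kind entered the comparisons. Of the probe sets, 19058 had an Entrez gene identifier in the RefSeq gene table of GRCh38.p14. Current symbols, chromosomes and the neighbourhood of each gene on its chromosome were taken from it, and no coordinates of it are reported. Each array was scaled to the same 2% trimmed mean, signals under the pooled 25th percentile (23.4) were set to it, and log2 was taken. Probe sets with a mean signal over the 3 arrays of at least the pooled 50th percentile (117) were kept, 11132 in all and 9899 with 1 gene. Each gene was represented by its probe set of highest mean signal, which gave 6745 genes.

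With 1 array per condition there is no test and no p-value, and nothing states whether the cultures were independent of each other. Genes are counted when at least 2-fold apart, and a gene is apart from both controls when the smaller of its 2 log2 differences has that size in the same direction. Each list of genes, 32 in all, was fixed before the data were examined, as were the groups, the settings, the alternatives and the rule for named genes. A list's median is placed among 10000 random lists of the same size matched on mean signal in 10 classes. This describes these arrays only. The brightest class spans mean signals from 3216 to 34942, so the match is loose for bright genes. Of the lists, 3 had fewer than 5 measured members. Genes are named by rule: MYCN, the 12 furthest above and the 12 furthest below both controls by the smaller difference, up to 4 members of each list by the same measure, and the 5 furthest each way between the controls. CDC25B, CKM, TNNI1, HSPH1, STIP1 and MYOG were chosen after their values were seen, and the list of ERK output genes after those of DUSP6, ETV4 and SPRY4 were.

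Both procedures were tested on simulated data with noise drawn from the control difference. For anti-MYCN PNA against both controls, over 6720 simulated genes, the 2-fold rule called 100% of genes changed 4-fold, 91.7% of those changed 3-fold, 38.8% of those changed 2-fold and 2.0% of those changed 1.5-fold, and 16 of 6524 unchanged genes. In a simulation of 28 unshifted lists 1 fell outside the 95% range. Alternatives were the signals as deposited, quantile normalization, median scaling, no filter, a filter at the 75th percentile, no floor, a pseudocount, thresholds of 1.5-fold and 3-fold, the median over a gene's probe sets, and probe sets without the suffixes _x_at and _s_at. Removing the chromosome neighbourhood was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.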

Results

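Gene expression was measured in RH30, a cell line from a human alveolar rhabdomyosarcoma, a childhood muscle-lineage tumour that often carries the PAX3-FOXO1 fusion. The cells had received a peptide nucleic acid (PNA, a DNA analogue with a peptide-like backbone) directed against the MYCN gene, a mutated PNA described as inactive, or nothing. Both PNAs were given at 10 µM and RNA was taken after 12 hours. There was 1 array per condition, 3 in all, so no value has a replicate error, no difference has a test, and every difference below is one between single arrays. Each array reported 22277 probe sets, and the median signal of its gene probe sets was 111 for untreated, 112 for mutated PNA and 127 for anti-MYCN PNA cells. The number of arrays limits the precision. The difference between the 2 control arrays is the only measure of background. For 95% of the 6745 genes compared, the controls differed by at most 0.57 on the log2 scale. The labels of the array called untreated disagree: its title and treatment text say untreated, and its source name says mutated PNA. It is called untreated here. Any direction between the 2 controls depends on that label, and so does any statement about 1 control taken singly.

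MYCN, the targeted gene, encodes a MYC-family transcription factor. Its brightest probe set gave a signal of 3313 in untreated, 2804 in mutated PNA and 2202 in anti-MYCN PNA cells. The anti-MYCN PNA value was thus 66.5% of untreated and 78.6% of mutated PNA, and mutated PNA was itself 84.6% of untreated. On the log2 scale the differences were −0.59 and −0.35. For 95% of the 674 genes of like signal the controls differed by at most 0.37, so MYCN lay beyond that range against untreated and within it against mutated PNA. Which control is which rests on the label of the untreated array. Of the same 674 genes, 155 were as low or lower than MYCN against mutated PNA and 75 against untreated. A dimmer MYCN probe set read 55.3, 29.8 and 17.4 in the same order, and the last value is below the floor of 23.4 used here. The third read 8.2, 9.0 and 11.3, below that floor on all 3 arrays.

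The spike and control probe sets set the anti-MYCN PNA array apart. All 24 probe sets for the bacterial poly-A spikes dap, lys, phe and thr, which in this kind of assay are added before labelling, were lower on it than on both controls. Their median ratio was 0.382 to mutated PNA and 0.410 to untreated, whereas mutated PNA over untreated gave 1.06. Hybridisation spikes had a median ratio to mutated PNA of 0.866 by the older 9 probe sets and 1.23 by the newer 9. Of the older 9, 8 were below 1, and all of the newer 9 were above 1. Mutated PNA over untreated gave 1.03 and 1.05. The signal ratio of 3′ to 5′ probe sets, a sign of RNA integrity, was 2.11 in untreated, 1.73 in mutated PNA and 1.99 in anti-MYCN PNA cells for beta-actin, and 1.02, 1.02 and 1.09 for GAPDH. Of the 8 pairs of poly-A spike probe sets, 5 had a higher ratio on the anti-MYCN PNA array than on both controls, such as phe at 2.91 against 1.53 and 1.58, and 3 a lower one, such as lys at 2.18 against 3.57 and 3.26. The 3 control probe sets for 18S ribosomal RNA read 0.461, 0.213 and 0.320 of mutated PNA on the anti-MYCN PNA array. RNA integrity, labelling and hybridisation are therefore not shown to be alike.

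The comparison of the anti-MYCN PNA with both controls asks which transcripts differ from each control in the same direction. It does not require the 2 controls to be alike. MON1B, called higher than both, read 27.0 in untreated, 107 in mutated PNA and 227 in anti-MYCN PNA cells. CACNG4 and CHPF lay furthest above both controls, and CFAP70, UBE2NL and LGR5 furthest below. In anti-MYCN PNA cells 78 genes were at least 2-fold higher and 85 at least 2-fold lower than on both controls. By the same rule the untreated array stood apart from the other 2 in 20 genes and the mutated PNA array in 16. In 100 simulations with no change, built from the control difference, the median count was 12 and the highest 21. The simulations hold no difference between whole arrays, such as the lower poly-A spikes, so they cannot show what such a difference would give. Against mutated PNA alone, 182 genes were at least 2-fold higher and 157 lower, and against untreated 207 and 156. The 2 comparisons share the anti-MYCN PNA array. Independent lists of these sizes would share 5.59 higher and 3.63 lower genes, but lists that share an array are not independent. No gene was called in opposite directions, which would need the 2 controls to lie far apart in that gene. Neither figure is therefore evidence for the genes called. The split depended on the scaling: for anti-MYCN PNA against both controls, quantile normalization gave 52 genes higher and 118 lower. Without a filter it was 622 and 182, and with the chromosome neighbourhood removed 36 and 68. Quantile normalization gave 146 and 200 for anti-MYCN PNA against mutated PNA, and 162 and 192 for anti-MYCN PNA against untreated.

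**Figure D1:**
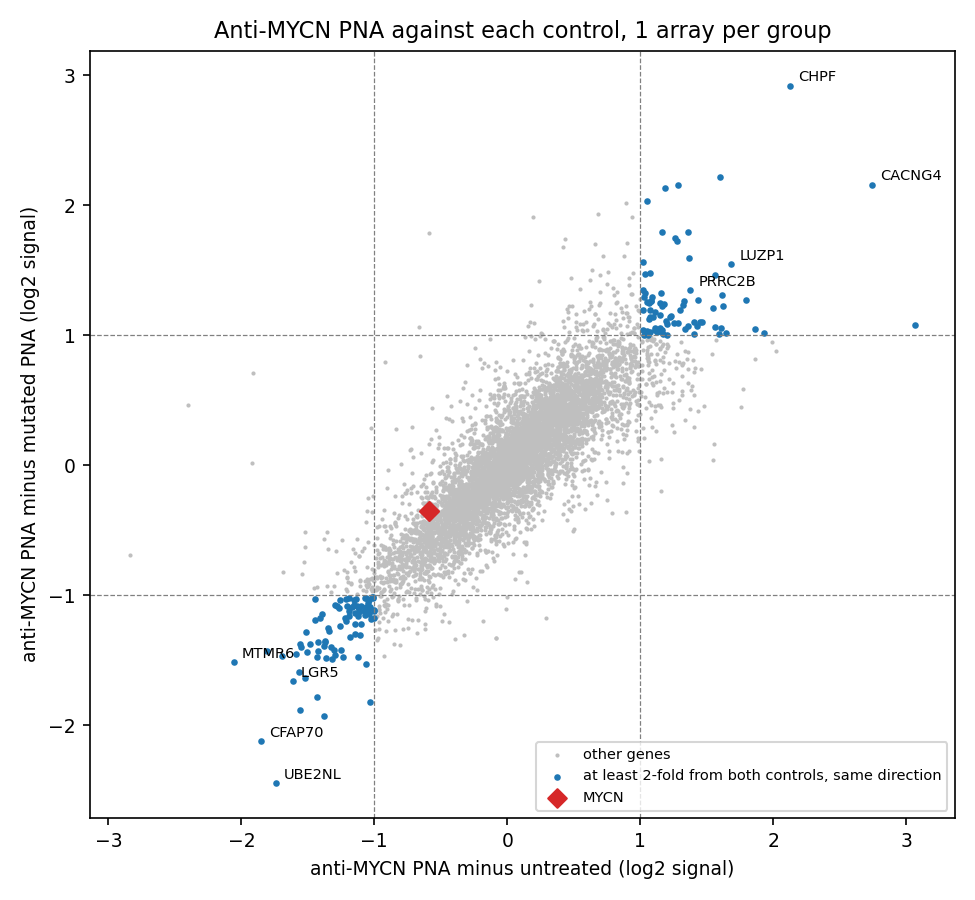
Log2 signal difference of anti-MYCN PNA to untreated (x axis) and to mutated PNA (y axis) for 6745 genes, 1 point per gene and 1 array per condition. Dashed lines mark 2-fold; 78 genes lie in the upper right corner and 85 in the lower left, and MYCN lies inside both lines at −0.59 and −0.35.

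Among the 12 genes furthest above both controls were CACNG4, an auxiliary subunit of calcium channels and glutamate receptors, with a signal of 438 against 65.5 in untreated and 97.9 in mutated PNA cells, and CHPF, a chondroitin-polymerising factor, with 939 against 215 and 124. LUZP1, a leucine zipper protein, read 804 against 251 and 275. ATN1, the transcriptional corepressor atrophin, read 548 against 185 and 198. PKMYT1, a kinase that holds CDK1 inactive, read 1399 against 542 and 462, and PRRC2B read 2570 against 991 and 1009. The proprotein convertase FURIN read 215 against 61.9 and 88.7, and the zinc finger gene ZNF580 read 723 against 299 and 219. TMEM204, NAAA, RAB3IL1 and the pseudogene ELK2AP completed the list, with smaller-of-the-2 log2 differences of 1.36, 1.31, 1.29 and 1.60. For CACNG4, FURIN, TMEM204, NAAA and ELK2AP both control signals lay below the filter of 117. These genes passed the filter only because of their anti-MYCN PNA signal.

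The 12 genes furthest below both controls included LGR5, a receptor for R-spondins, at 56.2 against 172 in untreated and 178 in mutated PNA cells, and the ephrin receptor EPHA7 at 97.0 against 288 and 293. ECT2, a guanine nucleotide exchange factor needed for cytokinesis, read 205 against 591 and 641. The replication nuclease DNA2 read 61.4 against 181 and 226, and the repair nuclease ERCC5 was below the nearer control by a log2 difference of −1.43. MTMR6, a phosphoinositide phosphatase, read 291 against 1214 and 831, and NEMF, of ribosome quality control, read 213 against 605 and 575. CFAP70, UBE2NL, BLTP3B, ZNF426 and TMEM38B completed the list, with log2 differences to the nearer control of −1.85, −1.74, −1.47, −1.45 and −1.43. For genes of the lowest signal class, such as LGR5 and DNA2, the controls themselves differed by up to 0.94 in 95% of genes. ELK2AP, TMEM204, NAAA and FURIN, among the higher genes, belong to that class too. Its median log2 difference of anti-MYCN PNA to the mean of the controls was 0.23, against 0.06 over all genes. Of the 24 genes, 7 were measured by a probe set with the suffix _x_at, whose probes also match other transcripts. They are PKMYT1, NAAA, ELK2AP, CFAP70, NEMF, TMEM38B and UBE2NL, a near copy of UBE2N. Each of them is uncertain for that reason.

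The mitosis list lay lower in anti-MYCN PNA cells, and the glycolysis, oxidative stress and muscle differentiation lists lay higher, as did ribosomal proteins except under quantile normalization. Of 29 lists with at least 5 measured members, 5 had a median outside the 95% range of random lists of like signal when anti-MYCN PNA was set against the mean of the controls, and 11 of 29 did between the 2 controls; 1.45 would be expected by chance if genes were independent, which genes of one pathway are not. The mitosis list was the one on the lower side: its 32 measured members had a median log2 difference of −0.19, at percentile 1.00, against 0.10 between the controls. None of them was 2-fold from both controls, 6 were at least 1.5-fold lower than both and none 1.5-fold higher. CCNB1, the cyclin that drives entry into mitosis, read 2578 against 4980 in untreated and 5094 in mutated PNA cells. The kinesin KIF23, the checkpoint kinase BUB1 and the mitotic kinase CDK1 were lower than the nearer control by log2 differences of −0.81, −0.65 and −0.63. Other members, such as CDC25B, a phosphatase that activates CDK1, with a log2 difference of 0.50, lay above both controls. The list also stood apart against mutated PNA and untreated taken singly, at percentiles 0.42 and 1.06.

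The other 4 lists lay on the higher side. The 24 measured ribosomal proteins had a median of 0.41, against 0.02 between the controls and above all 10000 random lists, and 23 of 24 were above both controls, with RPL32 at 33455 against 19550 and 20028 and RPS19 at 44735 against 27932 and 28445. Nearly all of these proteins fall in the brightest signal class, which reaches down to 3216, so their random lists also hold much dimmer genes. The same holds for bright glycolytic enzymes such as GAPDH. The direction depended on the scaling: with quantile normalization the list median of ribosomal proteins was −0.061. The exception in direction, RPLP2, was measured by a dim probe set that read 56.6 against 116 in untreated cells. Glycolytic enzymes had a median of 0.31 over 17 members, against −0.03 between the controls, with GAPDH, PKM, ALDOA and TPI1 above the nearer control by 0.66, 0.59, 0.57 and 0.48; 2 were at least 1.5-fold higher than both controls. Under quantile normalization the median was 0.16, at percentile 94.0, and without _x_at and _s_at probe sets it was 0.18, at percentile 83.0. Reference transcripts, a list that shares GAPDH and PGK1, had a median of 0.13 over 14 members, at percentile 72.7, with 4 at least 1.5-fold higher and none lower: POLR2A, ACTB, GAPDH and PPIA at 1.14, 0.67, 0.66 and 0.59. The list of oxidative and metal stress genes had a median of 0.33 over 18 members, against −0.08 between the controls, with 2 at least 1.5-fold higher: SLC7A11, the cystine transporter, at 214 against 114 and 78.9, and the metallothionein MT1G at 459 against 261 and 300. MT1G belongs to a family of near-identical genes and was measured by an _x_at probe set, so its own level is uncertain. Without _x_at and _s_at probe sets the list median was 0.10, at percentile 60.1, so the shift depended on such probe sets. Sarcomere and muscle differentiation genes had a median of 0.33 over 18 members, against 0.24 between the controls, and 0.18, at percentile 89.3, without _x_at and _s_at probe sets. CKB, brain-type creatine kinase, read 581 against 252 and 307, and ACTC1, cardiac actin, 27505 against 17091 and 19864. DMD, the dystrophin gene, went the other way at 463 against 1045 and 870. Against each control taken singly, ribosomal proteins were outside the random range both times. Glycolysis and oxidative stress genes were outside it against mutated PNA and inside it against untreated, at percentiles 92.8 and 92.1, and muscle genes were inside it against mutated PNA, at percentile 96.0. These 3 lists stayed outside the range under 5, 5 and 4 of 7 alternatives. Signals as deposited and no floor are among the 7 and left their percentiles unchanged. Muscle genes also fell inside the range under quantile normalization and with the chromosome neighbourhood removed, at percentile 96.2 each time. The lower poly-A spikes of the anti-MYCN PNA array accompany each of these shifts.

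The lists closest to MYCN did not stand apart against the mean of the controls. Of 31 measured genes known to be activated by MYC-family factors, none was 2-fold from both controls, 1 was 1.5-fold lower and the median was 0.04, at percentile 47.5. EIF4E, the cap-binding translation factor, and MAD2L1, a spindle checkpoint protein, were below the nearer control by −0.59 and −0.54, whereas SHMT2 and CDK4 were above it by 0.49 and 0.48, CDK4 not so under quantile normalization, which also brought the list median below 0. The 14 measured MYC-repressed genes had a median of 0.30, at percentile 96.3, and lay outside the random range against mutated PNA taken singly, at percentile 99.0, with DDIT3 at 3226 against 1672 and 1159, TIMP2 above the nearer control by 0.65 and ITGA6 and THBS1 below it by −0.74 and −0.61. The list of MYC, MAX and their partner proteins, which includes MYCN itself, had a median of 0.27 over 10 members, at percentile 91.0. The 26 measured PAX3-FOXO1 targets had a median of −0.08, at percentile 18.6; the receptor MET read 1254 against 2449 and 2994, and GREM1 was lower by −0.51. Among lineage genes CDH15, muscle cadherin, read 943 against 492 and 379, and DES, desmin, read 1609 against 911 and 923, within a list median of 0.20 at percentile 87.9.

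In the amino acid and unfolded protein stress list, 7 of 31 members were at least 1.5-fold higher than both controls and 1 was lower. Besides DDIT3, the factors ATF5 and ATF4 were above the nearer control by 0.83 and 0.79. The list median was 0.19, at percentile 93.6, and it lay at percentile 98.5 against mutated PNA taken singly and at the edge of the random range against untreated, with a median of 0.23 and an upper bound of 0.23. DNA replication genes had a median of −0.07 and a mean of 0.03, with E2F1 at 1012 against 464 and 496, 4 of 32 members at least 1.5-fold higher and none lower. The median was 0.02 with the median over probe sets and 0.03 without _x_at and _s_at probe sets. Of 20 p53 and apoptosis genes, BAK1, a pore-forming death effector, read 416 against 205 and 164, and XIAP, a caspase inhibitor, read 67.5 against 145 and 167. XIAP belongs to the lowest signal class. The median of that list was 0.12, at percentile 60.5, with 9 members above both controls and 6 below. In the nucleolar ribosome biogenesis list RRN3 and NIP7 were lower than both controls by −1.09 and −1.08 among 27 with a median of −0.05. That list lay just below the random range against untreated taken singly, with a median of −0.16 at percentile 2.29, and inside it against mutated PNA, at 0.14 and percentile 83.5. The 24 lists inside the random range had medians from −0.08 to 0.35, the highest being interferon-induced genes, where IFITM3, IFITM2 and IFITM1, close paralogues with similar sequence, were above the nearer control by 0.74, 0.66 and 0.64. Markers of other cells were mostly dim: 1 of 18 epithelial, 2 of 22 leukocyte and 1 of 14 endothelial markers passed the signal filter, and 13 of 27 fibroblast and matrix markers, with a median of 0.07. The endothelial marker was ENG at 458 against 205 and 196.

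**Figure D2:**
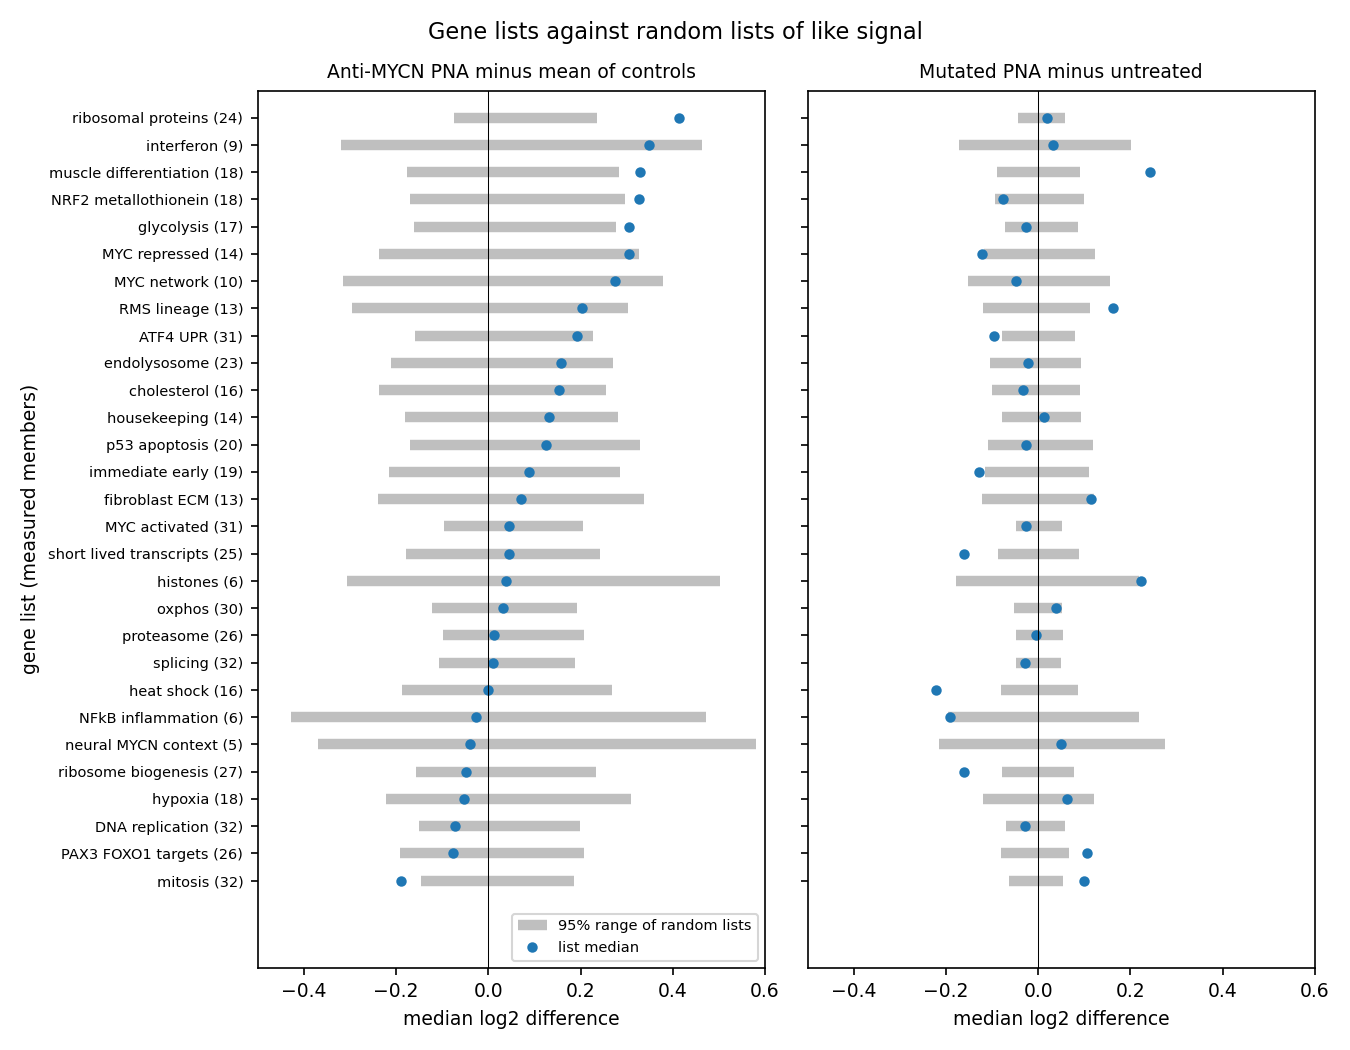
Median log2 difference of each gene list (points, measured members in brackets) with the 95% range of 10000 random lists of like signal (grey bars), for anti-MYCN PNA against the mean of both controls (left) and mutated PNA against untreated (right). Mitosis lies at −0.19 on the left and 0.10 on the right; ribosomal proteins lie at 0.41 and 0.02, and their 0.41 turns negative under quantile normalization.

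The ERK phosphatase gene DUSP6 and the genes ETV4 and SPRY4 were the furthest below untreated in mutated PNA cells, in the comparison of the 2 controls. In all, 25 genes were at least 2-fold higher and 25 lower in mutated PNA than in untreated cells, and the SD of the log2 difference over all genes was 0.28, against 0.51 for anti-MYCN PNA minus mutated PNA. The 5 furthest below untreated were DUSP6, a phosphatase that switches off ERK, at 206 against 1502, the ETS factor ETV4 at 50.1 against 307, the receptor signalling inhibitor SPRY4 at 88.3 against 457, EMP1 at 246 against 1094 and the small MAF factor MAFF at 112 against 427. At the same dose and time the anti-MYCN PNA array read 284 for DUSP6, 81.8 for ETV4, 305 for SPRY4, 153 for EMP1 and 113 for MAFF, so all 5 were below untreated on both PNA arrays, in 2 comparisons that share the untreated array, and SPRY4 was above mutated PNA by a log2 difference of 1.79. The 5 furthest above untreated were MON1B, PADI1, KLHL41, TGFB3 and PHF8, with log2 differences of 1.99, 1.51, 1.46, 1.39 and 1.35. The direction of each of these rests on the label of the untreated array.

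Although the 2 controls differed in few genes, 11 of the 29 lists had a median outside the random range in mutated PNA against untreated. The largest were muscle differentiation genes, higher by 0.24 over 18 members, with CKM, TNNI1 and TNNI2 at 0.65, 0.49 and 0.47, histone genes at 0.22 over 6 members, and cytosolic heat shock genes, with a median of −0.22 over 16 members and HSPH1 and STIP1 at −0.44 and −0.46. Short-lived transcripts and ribosome biogenesis genes each had a median of −0.16, and immediate early genes one of −0.13. Mitosis genes were 0.10 higher and PAX3-FOXO1 targets 0.11 higher, with MYOG, the myogenic factor myogenin, at 0.73. The remaining 3 were the lineage list at 0.16, the amino acid stress list at −0.10 and MYC-repressed genes at −0.12. The histone list stayed outside the range under 4 of 6 alternatives and the amino acid stress list under 4 of 7. Each of the others did so under at least 6 of 7.

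Differences of the anti-MYCN PNA array varied between chromosomes. The 435 measured genes of chromosome 19 had a median log2 difference of 0.33 to mutated PNA and 0.31 to untreated, and the 161 of chromosome 22 had 0.27 and 0.25. The 122 genes of chromosome 13 had −0.22 and −0.24, and the 227 of chromosome 4 had −0.14 and −0.12. The SD of the 23 chromosome medians was 0.143 against mutated PNA and 0.140 against untreated, and the largest values in 1000 shuffles of the genes were 0.0631 and 0.0605. For mutated PNA against untreated it was 0.0194, inside the shuffled range. With the median of the 20 nearest measured genes removed, an alternative added after seeing the data, anti-MYCN PNA against both controls gave 104 genes.

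**Figure D3:**
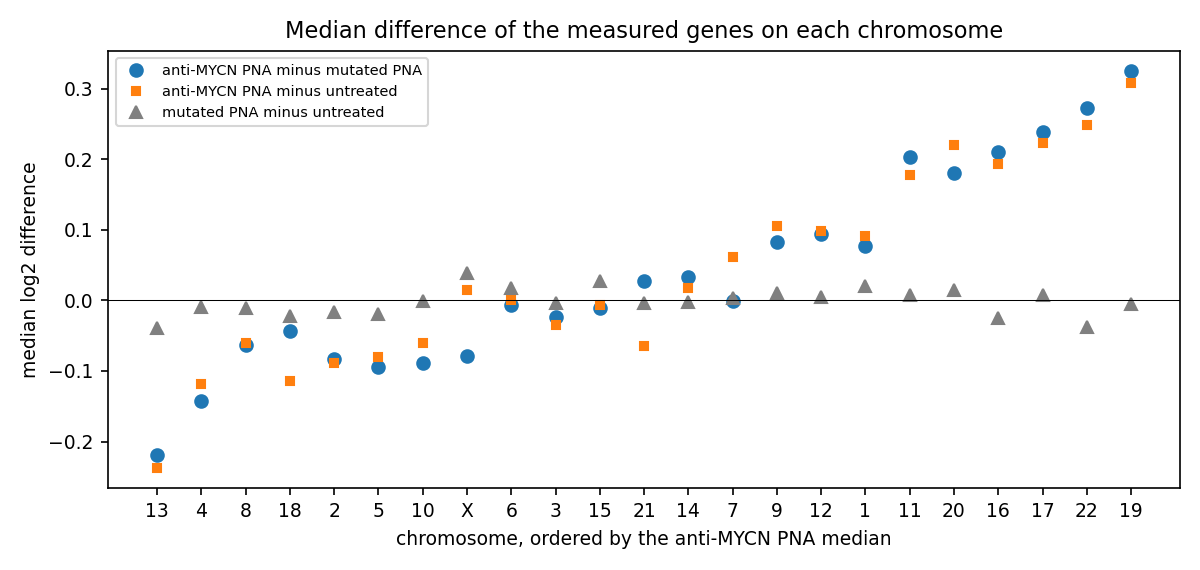
Median log2 difference of the measured genes on each chromosome, 1 point per chromosome and comparison, ordered by the anti-MYCN PNA median. Both anti-MYCN PNA comparisons run from about chromosome 13 (−0.22 and −0.24) to chromosome 19 (0.33 and 0.31), and the comparison of the 2 controls stays between −0.04 and 0.04.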

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

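The tests on further probe sets, poly-A spikes and shuffled genes were chosen after the results they bear on had been seen, and removal of the neighbourhood trend was added after seeing the data. Quantile normalization was fixed before the data were examined, and only its use as the test of the ribosomal protein shift was written after the result was seen. Outside the gene comparisons, 16 probe sets that name no gene or several genes were at least 2-fold higher on the anti-MYCN PNA array than on both controls and 17 lower, of 1233 that passed the signal filter; no such probe set was higher on the untreated or the mutated PNA array alone, and 1 and 3 were lower. They were singled out as a signal above the controls in data that entered no comparison. By the same rule 163 of the 6745 genes, or 2.42%, were called, so the rate is close to that among genes.

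The anti-MYCN PNA array stood at least 2-fold from both controls in 163 genes, 8.15 times the larger count of a control array. The tables argue against noise of single probe sets for the 44 of these genes with a further probe set above the filter. That probe set differed in the same direction in 90.9% (95% Wilson interval 78.8% to 96.4%). Probe sets of one gene can share probes, however, and only 4 repeated the 2-fold difference. Over all 2179 genes with 2 probe sets the differences to the controls correlated at 0.51, and those between the controls at 0.33. Such agreement is therefore not particular to the genes called. A smooth trend along chromosomes is not the whole of the pattern, since 104 genes were left once the neighbourhood median was removed. Of these, 80 were among the 163. A difference in RNA input, labelling or hybridisation stays open. The poly-A spikes were at a median ratio of 0.382 to mutated PNA, and the hybridisation spikes at 0.866 and 1.23. With 1 array per condition such a difference cannot be told apart from an effect of the anti-MYCN PNA, which is untested for the same reason.

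The chromosome medians of the anti-MYCN PNA array ran from chromosome 13 to chromosome 19 with an SD of 0.144 against the mean of the controls, where 1000 shuffles reached at most 0.0655, which argues against chance. Removing the trend on signal left 0.139, which argues against signal level. Across genes, which are not independent replicates, the correlation of a gene's difference with the median of its 20 nearest measured genes was 0.423 against mutated PNA and 0.0380 between the controls. Chromosomes 19, 22, 17 and 16 are known to be rich in G and C bases and chromosomes 13, 4 and 18 poor in them, so a candidate explanation is a dependence on base composition, which was not tested because no sequence was used here. The poly-A spike ratio of 0.410 to untreated lies on the same array, as do hybridisation spike ratios of 0.894 and 1.29. Input, labelling or hybridisation therefore cannot be told apart from an effect of the compound.

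The shift of the ribosomal protein list went with the scale of the brightest probe sets. Under quantile normalization its median went from 0.41 to −0.061, at percentile 19.4 of random lists, so the scaling may account for the shift. Whether quantile normalization removes a real difference in abundant transcripts was not tested, and an effect of the anti-MYCN PNA stays open.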

How the results depend on the processing

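No paired analysis was possible because each condition has 1 array, and for the same reason no replicate could be left out. The removal of the neighbourhood trend was chosen after seeing the data. Counts are given in this order: anti-MYCN PNA against mutated PNA, anti-MYCN PNA against untreated, anti-MYCN PNA against both controls, and mutated PNA against untreated, where the main counts are 339, 363, 163 and 50. Without a filter they were 1390, 1427, 804 and 546, and with the filter at the 75th percentile 93, 77, 37 and 7. At 1.5-fold they were 1602, 1583, 1055 and 315, and at 3-fold 31, 30, 6 and 9. Without _x_at and _s_at probe sets they were 215, 232, 99 and 26, with fewer genes tested. A pseudocount gave 102 against both controls and 28 between the controls, by construction, as it shrinks low signals. Removing the neighbourhood trend gave 104 against both controls. All other counts stayed within 1.5 times. At 3-fold the array counts lie close: the untreated array stood apart in 5 genes and the mutated PNA array in 2. For anti-MYCN PNA against both controls the split of 78 higher and 85 lower became 622 and 182 without a filter, 13 and 24 with the filter at the 75th percentile, 35 and 64 without _x_at and _s_at probe sets, and 36 and 68 with the neighbourhood removed. Of the 163 genes, 132 were shared with quantile normalization, 126 with the median over probe sets and 84 without _x_at and _s_at probe sets. Of the 24 named genes, 24 stayed 2-fold from both controls under quantile normalization and 22 with the neighbourhood trend removed. They had been picked as the furthest from both controls, so this is a weak check. MYCN stayed lower under all 5 alternatives run on it, from −0.29 to −0.35 against mutated PNA and from −0.53 to −0.72 against untreated. Of the 5 lists apart from random lists, mitosis stayed outside the range under 7 of 7 alternatives, ribosomal proteins under 6, glycolysis and oxidative stress under 5 and muscle differentiation under 4. Signals as deposited and no floor are counted among the 7 but gave the same percentiles as the main settings, so they are no check of these lists. The ribosomal protein median turned to −0.061 under quantile normalization. Between the controls, the amino acid stress list turned to 0.018 with the median over probe sets; the cause was not tested. The SD of chromosome medians was 0.0833 without a filter and stayed between 0.132 and 0.158 otherwise. Signal over background limits the dim genes: between 22.9% and 26.6% of gene probe sets lay at the floor per array.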

Other observations

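The ERK list below, and its test in the mutated PNA culture alone, were chosen after DUSP6, ETV4 and SPRY4 had been seen; the test on the list's other members in both cultures was fixed before their values were looked at, although CCND1 also belonged to 2 fixed lists already computed. How to read its missed bound was decided after the value was seen. The test of MYC-activated genes was written after the list's values were seen.

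Some genes known as outputs of the ERK pathway lay below untreated on both PNA arrays. Of a 10-gene list of ERK output genes, 8 were measured. Apart from DUSP6, ETV4 and SPRY4, whose low values prompted the list, 5 of 5 were lower on both PNA arrays than on the untreated array. Both comparisons share that array: with no change, 33.4% of simulated genes were lower on both, and 25.9% of all measured genes were. Part of the agreement may therefore come from the untreated array alone. The ETS factor ETV5 was below untreated by log2 differences of −1.73 in mutated PNA and −0.67 in anti-MYCN PNA cells. CCND1, cyclin D1, read 975 in untreated, 441 in mutated PNA and 822 in anti-MYCN PNA cells. The ephrin receptor EPHA2 was lower by −1.10 and −0.13, SPRY2 read 2411, 1634 and 1865, and PHLDA1 read 459, 304 and 310. These 5 genes were all higher in anti-MYCN PNA than in mutated PNA cells, with a median log2 difference of 0.90.

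A hypothesis is that ERK output was lower in the PNA-treated cultures, through the treatment or through handling such as a change of medium. The 5 other members had a median log2 difference of −1.10 in mutated PNA against untreated, below all 10000 random lists, which is consistent with it for that culture. In anti-MYCN PNA against untreated their median was −0.37, at percentile 6.16, so the bound of 2.5 set beforehand was missed. By that rule the prediction of lower ERK output in both cultures failed. The bound was missed by less than the SD of random lists, 0.27, with 5 of 5 lower. That reading was chosen afterwards, and the 5 of 5 rests on the shared untreated array. Against mutated PNA the same 5 genes lay at percentile 99.96. Immediate early genes, a fixed list that includes DUSP6, had a median of 0.09 in anti-MYCN PNA against untreated, at percentile 63.9. Lower ERK output in the anti-MYCN PNA culture is thus neither shown nor excluded. Treatment and handling cannot be told apart with 1 array each, and the source name of the untreated array leaves the direction between the controls open.

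A second hypothesis was that lower MYCN would show as lower MYC-activated genes at 12 hours. The median of that list lay at percentile 47.5 of random lists, with 18 of 31 members above both controls and 11 below. With members on both sides this neither shows nor excludes a change in MYC-family activity.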
